A study of Bubalus bubalis with 36 samples.

How the data were processed

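Small RNA libraries from adipose tissue of 6 buffaloes were analysed, each animal sampled at 6 depots, for 36 libraries. Per the labels' protocols, RNA was extracted with the RNeasy Lipid Tissue Mini Kit and libraries were made with the TruSeq RNA LT kit v2. The authors deposited a table of whole-number read counts per miRNA and library, not normalized, with RPM values (reads scaled to a common library total) beside them. The deposited RPM equalled the count divided by the library total on that scale, with a largest difference of 4.79e-06. The aligner, the miRNA caller and the genome build are not given in the sources used here. DESeq2 1.24.0 is listed in the submitters' processing notes, with no role. Features were named either as bovine miRNAs or by an identifier of a candidate locus that the table does not pair with a miRNA name, so those are reported by identifier or as unnamed loci. No coordinates are given. A blank line of the table held 0 counts and was left out. No column of another sample was present.

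Depot and animal were taken from the labels. Library totals ran from 9484589 to 13920998 counts, and 867 to 1052 features were detected per library. Counting error is a larger share of a low count, and its effect on the calls was not tested. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom between libraries was 912. The median correlation of libraries was 0.945 within and 0.935 between depots. The same 6 animals gave every depot, so the animal number pairs the libraries. Deviations from the depot means correlated by 0.198 on average between libraries of 1 animal and by −0.0392 between animals, and 64 of 90 pairs of the same animal exceeded 0.1.

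Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, robust glmQLFit, glmQLFTest), with TMM factors (0.745 to 1.26), a filter on low counts by filterByExpr (minimum count 10) and 1 coefficient per depot, with 30 residual degrees of freedom. All tests were two-sided. Subcutaneous against visceral was the mean of the 3 subcutaneous minus the mean of the 3 visceral depots. Each depot was set against the mean of the other 5, and F tests were made over all 6 depots and within each class. p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 for a call. The SE printed with a fitted log2 difference is the size of that difference divided by the square root of its quasi-likelihood F statistic. It was not estimated separately. CPM and log2 CPM (prior count 2) use TMM-scaled library sizes. An animal's direction is the sign of its own difference in mean log2 CPM.

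Named miRNAs of the class comparison were those called, with a mean of at least 10 CPM and the same direction in at least 5 of 6 animals, the 10 with the largest log2 fold change in each direction. Every tested HOX-cluster member and the 5 miRNAs with the highest mean were added. For each depot they were called miRNAs with at least 10 CPM in their highest depot and a depot mean log2 CPM beyond all other 5, the 3 with the largest increase and the 2 with the largest decrease. In each passing list 2 to 4 members with the smallest p were named.

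Lists were fixed as precursor names, 19 in all: HOX-cluster, skeletal and cardiac muscle, erythroid, leukocyte, endothelial, smooth muscle and stroma, kidney and gut epithelium, epithelial, neural, liver and pancreas, pro-adipogenic, anti-adipogenic, brown and beige fat, DLK1-DIO3 cluster, miR-17-92 and paralogues, miR-424 and miR-503 cluster, miR-29 family, miR-30 family and let-7 family. Lists with at least 3 tested members, 17 of them, were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists, and over all 102 pairs of list and depot. Camera with an estimated correlation was run beside it. Groups, tests, lists, the naming rule and the alternatives of the next paragraph, other than those said to be chosen later, were fixed before the data were examined.

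The alternatives were RLE factors, library totals alone, no filter, a mean of at least 10 CPM, the animal as a block, the library letter as a covariate, letter B libraries alone, each animal left out, limma on log2(RPM + 1), DESeq2 1.42.0, 2 groups of 18 libraries, counts summed per animal and class, and only the most abundant arm of each precursor in the lists. After the data were seen, libraries BSAT2, or PRAT2 and PRAT6, were left out, each of the 36 libraries was left out in turn, the perirenal or the pericardial depot was left out, and miR-26a and miR-26c were summed.

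The fits were tested on simulated counts with known changes. For subcutaneous against visceral, with 653 features tested, 25.8% of 1.5-fold, 42.2% of 2-fold and 93.9% of 4-fold changes were recovered, with 0 false calls among 457 unchanged features. For pericardial fat, with 651 tested, 6.15%, 41.8% and 75.4% were recovered, with 5 false calls (5.81% of calls). Smaller differences were therefore often missed. Each simulated library was drawn independently from the fitted model, without an animal effect or single deviating libraries. The false calls are therefore those of that model, not of the real counts. With the real counts, depot labels shuffled inside animals gave up to 5 calls between the classes and up to 19 in pericardial fat.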

Results

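MicroRNA (miRNA) was sequenced from adipose tissue of 6 buffaloes, each sampled at the same 6 depots, which gave 36 libraries. The subcutaneous depots were the back (BSAT), the sternum (SSAT) and the inguinal region (IAT). The visceral depots were omental (OAT), pericardial (PCAT) and perirenal (PRAT) fat. Every depot had 6 libraries, 1 per animal, so each class had 18. Per the labels, the animals were weaned at 3 months, fattened from 15 months and slaughtered at 20 months of age. Library totals ran from 9484589 to 13920998 counted reads with a median of 12525362. They averaged 12558907 ± 953551 in subcutaneous and 12246578 ± 916801 in visceral libraries (SD, n = 18 each). The table held 1682 features, of which 695 carried bovine miRNA names and 987 were candidate loci without a miRNA name. Candidate loci took 23.3% of all counts, and the 10 most abundant features of a library took 48.5% to 59.6% of its counts. After low counts were removed, 667 features were tested, 389 with miRNA names and 278 candidates. Their biological coefficient of variation was 0.731. Reads of near-identical family members (miR-196a and miR-196b, miR-23a and miR-23b, miR-27a and miR-27b, miR-199a and miR-199b, miR-26a and miR-26c, the miR-148 and let-7 families) can be divided between features by counting, so the value of any member alone is uncertain.

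Subcutaneous and visceral fat were compared to find the miRNAs that mark each class. miRNAs of the HOX clusters, genomic regions whose genes set position along the body axis, were higher in the subcutaneous class. On the log2 scale miR-196b was higher by 3.75 ± 0.45 (SE) and miR-196a by 3.11 ± 0.41, both in 6 of 6 animals. Perirenal fat was apart from the other visceral depots in this group: miR-196b averaged 2629 ± 1198 CPM there (SD, n = 6), against 85.9 ± 156 CPM in omental and 14.9 ± 11.1 CPM in pericardial fat. In visceral fat the miR-200 family, known for keeping cells epithelial, was higher: the log2 fold change of subcutaneous over visceral was −5.16 ± 0.95 for miR-200a and −4.57 ± 0.90 for miR-429. miR-9-5p, a miRNA best known from neural tissue, was also lower in subcutaneous fat (−2.27 ± 0.27), and all 3 were lower in 6 of 6 animals. The rise of miR-200a did not reach every visceral library. OAT1, OAT3, OAT5, PCAT1, PRAT1, PRAT3 and PRAT4 held 1.71 to 18.5 CPM, within the subcutaneous range of 0.289 to 35.4 CPM. The remaining visceral libraries held 44.8 to 1562 CPM. edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 2.67e-07 for miR-196b, 9.02e-07 for miR-196a, 2.68e-04 for miR-200a, 6.21e-04 for miR-429 and 2.67e-07 for miR-9-5p.

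Of the 667 features tested, 110 differed between the classes, 48 higher and 62 lower in subcutaneous fat. Among them 61 differed at least 2-fold, 24 higher and 37 lower. miR-23a averaged 9467 ± 5575 CPM (SD, n = 18) in subcutaneous and 2719 ± 815 CPM in visceral libraries, a log2 difference of 1.73 ± 0.21 (adjusted p = 2.67e-07). miR-27a-5p was higher by 1.76 ± 0.33 (adjusted p = 2.98e-04) and miR-199b by 1.47 ± 0.18 (adjusted p = 2.67e-07), each in 6 of 6 animals. miR-148c (1.68 ± 0.42), miR-214 (1.49 ± 0.42) and miR-152 (1.41 ± 0.34) were higher in 5 of 6 animals. The unnamed candidate loci NC_059178.1_42973 (1.69 ± 0.55, 5 of 6 animals) and NC_059165.1_25336 (1.55 ± 0.38, 6 of 6 animals) were higher too. On the visceral side miR-449a averaged 169 ± 243 CPM in visceral against 40.0 ± 17.4 CPM in subcutaneous libraries. Its log2 fold change was −1.88 ± 0.40 (adjusted p = 0.00143), and it was lower in 6 of 6 animals. The rise of miR-449a did not reach every visceral library. OAT1, OAT3, OAT5, OAT6, PCAT1, PRAT1, PRAT2, PRAT5 and PRAT6 held 25.5 to 70.2 CPM, within the subcutaneous range of 9.22 to 72.3 CPM. The remaining visceral libraries held 81.5 to 962 CPM. miR-218 (−1.30 ± 0.28), miR-138 (−1.60 ± 0.48), miR-2285bb (−1.20 ± 0.29) and the candidate locus NC_059163.1_21335 (−1.42 ± 0.41) were lower in 6 of 6 animals. The liver miRNA miR-122 (−3.44 ± 0.86) and the leukocyte miRNA miR-142-5p (−1.93 ± 0.55) were lower in 5 of 6.

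The most abundant miRNAs differed little between the classes. let-7i was higher in subcutaneous fat by 0.41 ± 0.12 (adjusted p = 0.0173, 5 of 6 animals) and let-7c by 0.49 ± 0.17 (adjusted p = 0.0436, 6 of 6 animals). miR-451, an erythroid miRNA, was at 50836 ± 47597 CPM in subcutaneous and 51449 ± 24775 CPM in visceral libraries (log2 difference −0.31 ± 0.25, adjusted p = 0.425). miR-26a averaged 66753 ± 52704 CPM in subcutaneous and 55660 ± 49047 CPM in visceral libraries (log2 difference 0.27 ± 0.50, adjusted p = 0.729). The most abundant candidate locus differed by −0.01 ± 0.27 (adjusted p = 0.983). The level of miR-26a fell into separate clusters of libraries: it took 88.9% to 97.3% of the summed miR-26a and miR-26c counts in 19 libraries and 4.95% to 18.6% in the other 17. The sum of the pair averaged 109365 ± 24035 CPM (SD, n = 36).

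**Figure D1:**
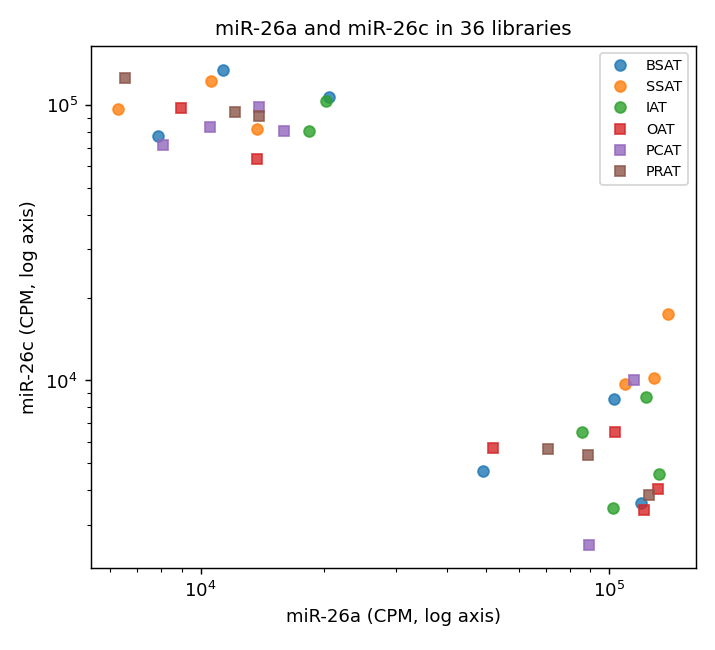
Level of miR-26c (y axis, CPM, log axis) against miR-26a (x axis, CPM, log axis) in the 36 libraries, coloured by depot. The libraries form a cluster of 19 with mostly miR-26a and a cluster of 17 with mostly miR-26c, and every depot has libraries in both.

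Of 17 lists fixed in advance and tested, 5 passed between the classes. All 5 tested HOX-cluster miRNAs were higher in subcutaneous fat (adjusted p of the list 4.36e-12), and 5 were called when adjusted over the list alone. With an estimated correlation the adjusted p was 3.61e-05. Not every visceral depot was low in the mean score of this list, the mean centred log2 CPM of its tested members. Perirenal fat was at 1.33, above back (1.04) and sternal fat (0.64) and below inguinal fat (1.57). Omental (−1.34) and pericardial fat (−3.24) were the low depots. Besides the miR-196 pair, miR-10b was higher by 1.26 ± 0.17 and miR-10a by 0.82 ± 0.21, while miR-615 (1.58 ± 0.45) lay below 1 CPM. In the smooth muscle and stroma list 3 of 6 tested members rose, miR-199b, miR-214 and miR-199a-5p (0.83 ± 0.23), and 3 when adjusted over the list alone (list adjusted p = 0.00317). Its adjusted p = 0.166 with an estimated correlation. In the epithelial list 5 of 6 members were lower in subcutaneous fat, among them miR-200b (−5.42), miR-141 and miR-200c. Adjusted over the list alone, 5 were lower and 1 (miR-183, 1.01 ± 0.47) was higher, and the list had an adjusted p of 0.00434. Its adjusted p = 0.337 with an estimated correlation. Of 36 tested miRNAs of the imprinted DLK1-DIO3 cluster 9 were lower in subcutaneous fat, 12 when adjusted over the list alone, led by miR-411c-3p (−1.44 ± 0.28), miR-370 (−2.01 ± 0.43) and miR-493 (−0.94 ± 0.23). The list's adjusted p was 4.17e-05, and its adjusted p = 0.508 with an estimated correlation. The depots of the 2 classes overlapped in the mean score of this list. Pericardial fat was high (0.91) and sternal fat low (−0.64). Perirenal fat (−0.21) was near back fat (−0.19), and omental fat (0.06) was near inguinal fat (0.08). The brown and beige fat list passed with an adjusted p of 0.0495. Of its 13 tested members miR-196a and miR-193a-5p (0.72 ± 0.24) were higher, and adjusted over the list alone miR-32 (−0.57 ± 0.21) was lower besides. This list had an adjusted p = 0.169 with an estimated correlation and an adjusted p of 0.0502 with the animal as a block.

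The other 12 lists did not pass between the classes, with adjusted p-values from 0.102 (miR-424 and miR-503 cluster) to 0.521 (kidney and gut epithelium). In the leukocyte list 3 of 7 members were lower in subcutaneous fat (5 when adjusted over the list alone), miR-142-3p by −2.51 ± 0.65, miR-142-5p and miR-146a (−0.96 ± 0.33). In the list of miRNAs reported to hold back fat cell formation 4 of 17 members were higher, miR-224 (1.01 ± 0.17), miR-27a-3p (0.81 ± 0.15), miR-27a-5p and miR-27b (0.51 ± 0.15), and 1 was lower, miR-138. Over the list alone 4 were higher and 2 lower, and the list's median (−0.15) lay below 0 while its test pointed up. In the pro-adipogenic list, of 23 members, miR-103 was higher (0.52 ± 0.14) and miR-17-5p (−1.36 ± 0.43) and miR-335 (−1.15 ± 0.41) were lower, with 1 and 1 over the list alone. In the neural list 1 of 9 members was lower, miR-9-5p, and 1 over the list alone, with a median of 0.06 and a test that pointed down. Of 6 muscle miRNAs miR-499 was lower (−0.73 ± 0.24), as it was over the list alone. The miR-17-92 list had 2 of 14 members lower, miR-17-5p and miR-18b (−1.05 ± 0.35), and 2 over the list alone. In the let-7 family let-7i and let-7c were the 2 members of 10 that were higher, also over the list alone. None of the 3 erythroid, 3 kidney and gut, 5 miR-29 and 6 miR-30 members passed in edgeR, nor did any over the list alone. None of 6 miR-424 and miR-503 members passed over all features, while 3 were lower over the list alone. The endothelial list and the liver and pancreas list had 2 tested members each and were not tested as lists. The endothelial median was 0.37, with 0 called and 1 higher over the list alone, and in the other list miR-122 was lower, also over the list alone.

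The split of calls depended on scaling. It was 43.6% higher with TMM factors, 18.8% (26 higher, 112 lower of 138) with library totals alone and 19.3% (22 and 92 of 114) in limma on log2(RPM + 1). Library totals moved the median of all features from −0.09 to −0.29 and the RPM fit to −0.18, so a difference near 0 is relative to that shift. Each library name also carries a letter, A or B, whose meaning the labels do not give, and 7 of the 8 letter A libraries were visceral and 1 subcutaneous. Within letter B, 39 features differed, 19 higher and 20 lower, and 16 of the 25 called miRNAs named here passed. They included miR-196b (3.70), miR-196a (2.97), miR-23a (1.71), miR-200a (−4.14) and miR-9-5p (−2.05). The other 9 were not called: NC_059178.1_42973 (1.26), miR-148c (1.59), NC_059165.1_25336 (1.54), miR-214 (1.45), miR-152 (1.31), miR-142-5p (−1.98), miR-138 (−1.79), let-7c (0.45) and let-7i (0.35). With the letter as a covariate in all 36 libraries 71 features differed, and NC_059178.1_42973 (1.44), let-7c (0.48) and let-7i (0.36) were not called. The letter itself was called in 7 of 667 features. Within letter A too few subcutaneous libraries exist for a value. Libraries of 1 animal enter the test as if independent; counts summed per animal and class, with the animal as the unit, called 23 features, or 46 with animals as blocks. Summed in this way, 15 named calls were lost: NC_059178.1_42973, miR-148c, miR-214, miR-152, miR-122, miR-138, miR-10a, miR-615, let-7c and let-7i, which were not called with the block either, and miR-142-5p, miR-449a, NC_059163.1_21335, miR-218 and miR-10b. With animals as blocks NC_059178.1_42973 (0.98), miR-214 (0.95), miR-122 (−1.49) and let-7c (0.46) were not called.

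The HOX-cluster difference rested on how the depots of a class were weighed. With 2 groups of 18 libraries, in which depot differences enter the spread, miR-196b (1.26), miR-196a (1.16), miR-10a (0.52), miR-10b (0.80), miR-615 (0.99), miR-138 (−1.27) and let-7c (0.49) were not called. Without the pericardial depot, a setting chosen after the data were seen, 54 features differed. There miR-196a (1.23), miR-10b (0.46), miR-615 (0.44), miR-2285bb (−0.77), miR-214 (1.37) and NC_059178.1_42973 (1.77) were not called, and miR-10a turned to −0.11. Without the perirenal depot NC_059165.1_25336 (0.93), NC_059178.1_42973 (1.43), miR-148c (1.42), miR-122 (−2.15), miR-138 (−1.26), let-7c (0.39) and let-7i (0.37) were not called. Single libraries weighed on some values. NC_059178.1_42973 was 0.86 without SSAT1, 1.16 without IAT1 and 1.48 without BSAT3, and miR-138 was −1.27 without OAT2, none of them called. let-7c lost its call without any 1 of 17 libraries. miR-122 stayed called at −2.43 without PRAT6, −2.73 without PCAT6 and −2.80 without OAT6. miR-200a stayed called at −4.13 without PRAT2, −5.85 without BSAT6 and −6.15 without IAT6, and miR-429 at −3.74, −5.18 and −5.47. miR-196b was 4.41 without OAT2, and miR-615 was 2.40 without PCAT2.

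**Figure D2:**
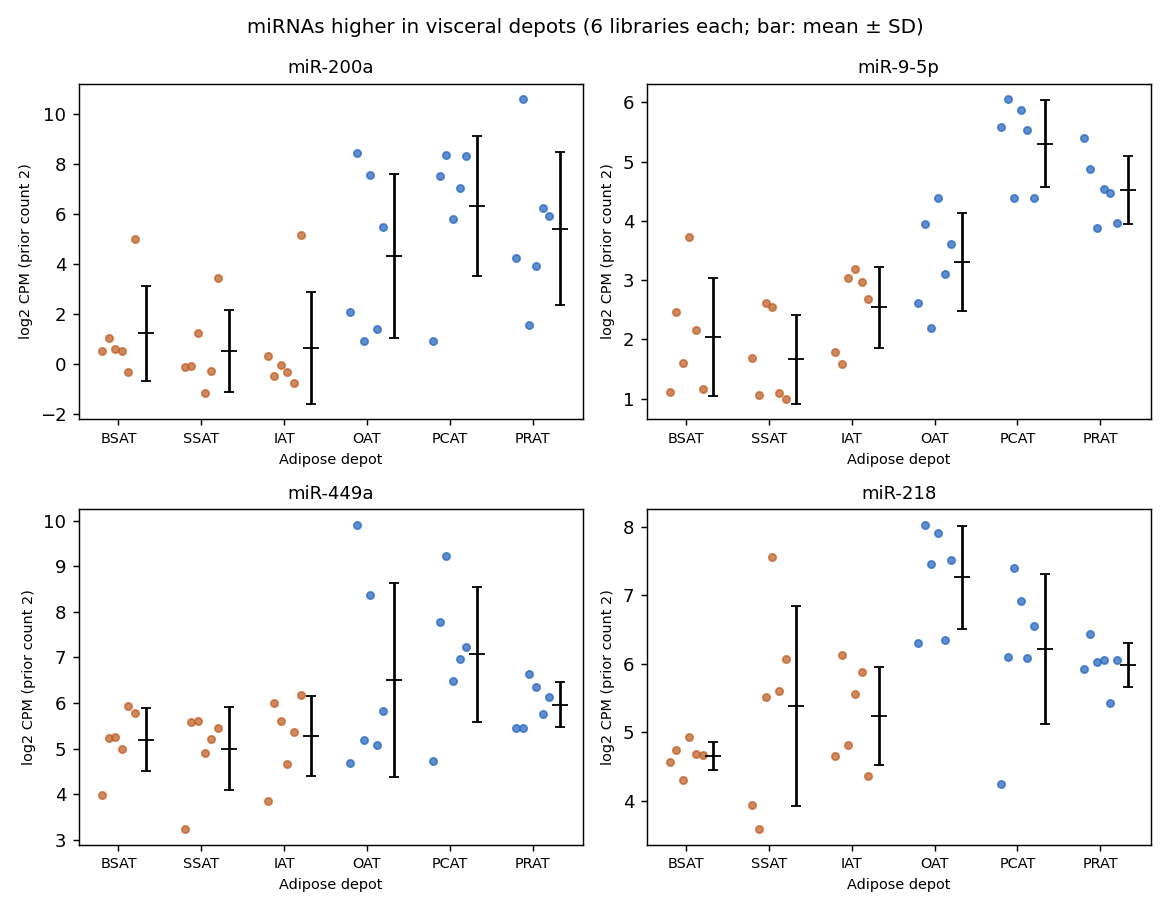
Log2 CPM (y axis) of miR-200a, miR-9-5p, miR-449a and miR-218 by depot (x axis), with 6 libraries per depot as points and the mean ± SD as bars. miR-9-5p averaged 43.4 CPM in pericardial fat and 3.40 CPM in sternal fat.

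Each depot was set against the mean of the other 5 to find what sets it apart. Back fat (BSAT) carried more of the red blood cell miRNAs miR-486 and miR-451, and more miR-223, while the leukocyte list as a whole did not pass. miR-486 averaged 253 ± 147 CPM (SD, n = 6) against 81.4 ± 47.3 CPM in the other 30 libraries, a log2 difference of 1.68 ± 0.33 (adjusted p = 0.00215). miR-451 was higher by 1.33 ± 0.31 (adjusted p = 0.0110) and miR-223 by 1.30 ± 0.35 (adjusted p = 0.0405), and all 3 were higher in 6 of 6 animals. miR-223 was the 1 called of 7 leukocyte members, also over the list alone, and that list had an adjusted p of 0.628 and a median of −0.75, with miR-142-5p at −1.59 ± 0.81 and miR-150 at −0.93 ± 0.51, neither called. miR-218 (−1.60 ± 0.42) and miR-1247-5p (−1.96 ± 0.54) were lower in 6 of 6 animals. In total 15 features differed, 11 higher and 4 lower, and 40 with no filter. The erythroid list passed (2 of 3 members higher, 2 over the list alone, adjusted p = 6.08e-04), with an adjusted p = 0.0868 with an estimated correlation. HOX-cluster miRNAs rose as a list (2 of 5 higher, 3 over the list alone, adjusted p = 5.33e-06, and 0.00557 with an estimated correlation), miR-196a by 2.37 ± 0.43 and miR-196b by 2.36 ± 0.47. This rise was not particular to back fat, whose mean list score (1.04) lay below inguinal (1.57) and perirenal fat (1.33). The mean of the other depots includes omental (−1.34) and pericardial fat (−3.24), which were low. The DLK1-DIO3 list passed downward with 0 of 36 members called, also over the list alone (adjusted p = 0.0239). Its adjusted p = 0.780 with an estimated correlation. Of the skeletal and cardiac muscle list, which did not pass, miR-206 was at 4.12 ± 0.69 and miR-133b at 2.82 ± 0.79, and the back library of animal 2 held 2228 CPM of miR-206 against 2.20 to 70.5 CPM in the other back libraries. Without that library 7 features differed, and miR-486 (1.35), miR-451 (1.03) and miR-223 (0.99) were not called. Without BSAT6, 6 features differed and miR-451 was not called. miR-223 lost its call without any 1 of 25 libraries, miR-1247-5p of 10 and miR-218 of 4. Within letter B 11 features differed, miR-1247-5p and miR-218 (−1.59) were not called, and in the full set the share of higher calls was 73.3%, or 60.0% in limma and 52.4% in DESeq2.

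Sternal fat (SSAT) was low in miRNAs of the DLK1-DIO3 cluster and high in miR-148c and stromal miRNAs. Of 36 DLK1-DIO3 members 12 fell, 16 over the list alone, among them miR-381 (−1.75 ± 0.39), miR-411a (−1.18 ± 0.27), miR-493 (−1.42 ± 0.34) and miR-370 (−2.08 ± 0.66). The list's adjusted p was 4.53e-09, and its adjusted p = 0.346 with an estimated correlation. miR-148c averaged 207 ± 314 CPM against 41.6 ± 52.4 CPM elsewhere (2.47 ± 0.47, adjusted p = 9.15e-04), higher in 6 of 6 animals. miR-199b (1.46 ± 0.21) and miR-214 (1.75 ± 0.49) rose within the smooth muscle and stroma list (2 of 6 members, 3 over the list alone, adjusted p = 0.0225). Its adjusted p = 0.346 with an estimated correlation. The mean score of the stroma list was 0.43 ± 0.64 (SD, n = 6) in sternal, 0.32 ± 0.35 in back and 0.23 ± 0.43 in inguinal fat. This rise was therefore not particular to sternal fat. In the F test among the subcutaneous depots neither miR-148c nor any stroma or DLK1-DIO3 member was called. miR-214 averaged 172 ± 255 CPM (SD) in sternal and 126 ± 197 CPM in inguinal fat. The sternal libraries ran from 18.3 to 680 CPM, so 1 library weighed heavily on that mean. In the HOX list miR-10a (1.51 ± 0.25) and miR-10b (0.92 ± 0.21) rose, 2 of 5 members and 3 over the list alone (adjusted p = 0.00161). Its adjusted p = 0.0702 with an estimated correlation. The mean score of the HOX list in sternal fat (0.64) lay below back (1.04), inguinal (1.57) and perirenal fat (1.33). let-7i (0.78 ± 0.15) and miR-98 (0.52 ± 0.15) rose, 2 of 10 let-7 family members and 2 over the list alone (adjusted p = 0.0239). That list had an adjusted p = 0.615 with an estimated correlation. miR-451 (−1.43 ± 0.38) was the 1 called of 3 erythroid members, with 2 lower over the list alone (adjusted p = 0.0334). That list had an adjusted p = 0.395 with an estimated correlation. The miR-424 and miR-503 list passed downward with 0 of 6 members called and 2 over the list alone (adjusted p = 0.0139). Its adjusted p = 0.604 with an estimated correlation. In all 62 features differed, 37 higher and 25 lower, a share of 59.7% higher that was 28.1% with library totals, 70.8% with RLE factors and 17.9% in limma. DESeq2 called 97 features, and 30 were called with no filter. miR-138 (−2.27 ± 0.75, 6 of 6 animals lower) and the candidate locus NC_059178.1_42973 (2.66 ± 0.61, 4 of 6 animals higher) were also apart. Without SSAT1 26 features differed, miR-148c (1.23) and NC_059178.1_42973 (0.29) were not called, and without SSAT4 22 features differed. Another candidate locus (2.40 ± 0.64, 2 of 6 animals higher) was 0.09 without SSAT1. With animals as blocks neither NC_059178.1_42973 (1.56) nor the other locus (1.32) was called. miR-138 lost its call without any 1 of 26 libraries and miR-370 without any sternal library. Within letter B 25 features differed. There miR-148c was 2.37 and stayed called, while NC_059178.1_42973 (2.35), the other locus (2.09), miR-138 (−2.37) and miR-370 (−1.94) were not called.

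Inguinal fat (IAT) had the highest mean levels of the miR-196 pair. High levels were shared with perirenal fat, at 2629 ± 1198 CPM (SD, n = 6) for miR-196b and 216 ± 84.0 CPM for miR-196a. Back fat held 2143 ± 1342 and 124 ± 77.5 CPM. The mean of the other depots includes omental and pericardial fat, which were low. miR-196a averaged 360 ± 176 CPM against 73.4 ± 98.3 CPM in the other depots (4.21 ± 0.41, adjusted p = 5.03e-09), and miR-196b 3229 ± 1633 against 1211 ± 1375 CPM (3.07 ± 0.46, adjusted p = 3.66e-05), both in 6 of 6 animals. These were the only 2 features called by edgeR, with 46 at an unadjusted p under 0.05, and limma and DESeq2 called 2 each. With no filter 21 features were called, all higher. Within letter B 2 features differed, and 4 differed without SSAT6, OAT2 or PRAT2. The HOX list passed (2 of 5 higher, 4 over the list alone, adjusted p = 1.54e-16, and 5.13e-06 with an estimated correlation). The brown and beige fat list passed through miR-196a, its 1 called member of 13, and 1 over the list alone (adjusted p = 0.00639). Its adjusted p = 0.0702 with an estimated correlation. The epithelial list pointed down, with an adjusted p of 0.0421 with animals as blocks and 0.0849 without. Without blocks and with an estimated correlation the epithelial list did not pass either.

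**Figure D3:**
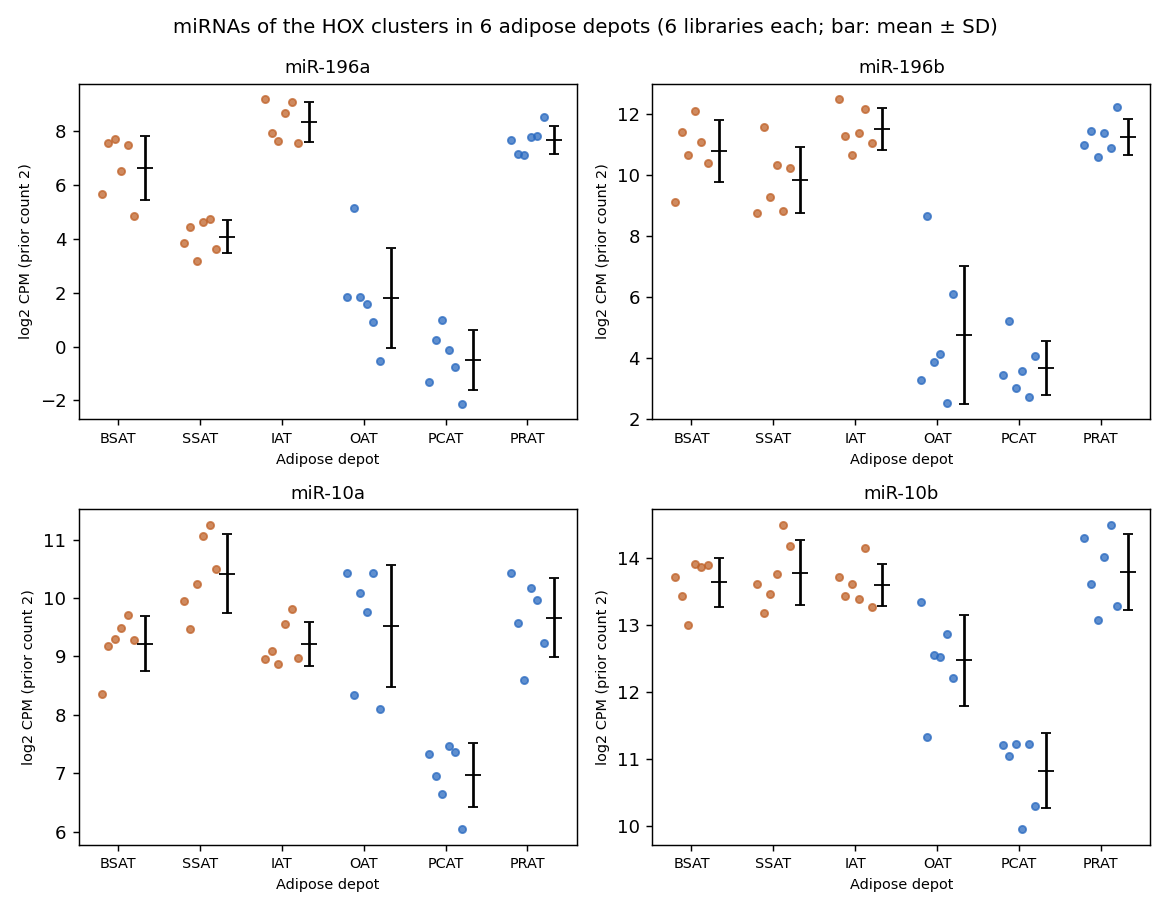
Log2 CPM (y axis) of miR-196a, miR-196b, miR-10a and miR-10b by depot (x axis), 6 libraries each as points with the mean ± SD as bars. miR-196a averaged 360 CPM in inguinal, 216 CPM in perirenal and 0.728 CPM in pericardial fat.

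Omental fat (OAT) was high in miR-218 and low in miR-23a and the miR-196 pair. miR-218, a miRNA of the SLIT gene introns, averaged 170 ± 76.7 CPM against 56.7 ± 42.4 CPM elsewhere (1.71 ± 0.33, adjusted p = 0.00550), higher in 6 of 6 animals. miR-23a was lower in 6 of 6 animals (−1.19 ± 0.30, adjusted p = 0.0398). Low miR-23a was shared by the visceral depots, with means of 2490 CPM in omental, 2786 CPM in pericardial and 2880 CPM in perirenal fat. The subcutaneous means were 6686 to 13648 CPM. miR-196b (−3.21 ± 0.70) and miR-196a (−2.42 ± 0.61) fell, 2 of 5 HOX-cluster members, and 3 lower and 1 higher over the list alone (adjusted p = 0.00161). Its adjusted p = 0.0830 with an estimated correlation. Pericardial fat was lower still in the miR-196 pair, 14.9 against 85.9 CPM for miR-196b and 0.728 against 7.82 CPM for miR-196a. miR-199b fell (−0.96 ± 0.26), 1 of 6 smooth muscle and stroma members and 1 over the list alone (adjusted p = 0.00586). Its adjusted p = 0.222 with an estimated correlation. The leukocyte miRNA miR-142-3p (3.02 ± 0.69, adjusted p = 0.0200) was higher in 3 of 6 animals, and its level reached 129 CPM in the omental library of animal 2. Without that library its value was 1.79, not called, and 4 features differed. The candidate locus NC_059163.1_21335 was higher by 1.84 ± 0.48 in 5 of 6 animals. With animals as blocks miR-142-3p (2.56), that locus (1.67) and miR-23a (−1.21) were not called, and 3 features differed. In all 10 features differed, 6 higher and 4 lower (60.0% higher, 75% with library totals, 28.6% in limma), and 2 within letter B, where none of miR-218, miR-23a, miR-142-3p and the locus was called. The count was 7 in limma or with the letter as a covariate, 19 in DESeq2, 20 with library totals and 126 with no filter. Leaving out 1 library at a time gave 4 to 27, with 27 without OAT1, 22 without BSAT3 and 16 without SSAT1 or IAT6. miR-23a lost its call without any 1 of 21 libraries and the locus without any 1 of 14.

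Pericardial fat (PCAT) was the depot with the lowest means of the HOX-cluster miRNAs and the highest of the DLK1-DIO3 miRNAs. miR-196a averaged 0.728 ± 0.644 CPM against 145 ± 160 CPM in the other depots (−6.51 ± 0.80, adjusted p = 3.76e-07), and miR-196b 14.9 ± 11.1 against 1853 ± 1571 CPM (−6.25 ± 0.85, adjusted p = 1.74e-06). miR-10b (−2.62 ± 0.28), miR-10a (−2.69 ± 0.35) and miR-615 (−3.58 ± 0.80, with 0 counts in 5 of 6 pericardial libraries) fell too, so 5 of 5 HOX-cluster members fell, 5 over the list alone (list adjusted p = 4.17e-18, and 1.08e-06 with an estimated correlation). Of 36 DLK1-DIO3 members 18 rose, 27 over the list alone, among them miR-411c-5p (1.47 ± 0.26), miR-381 (1.56 ± 0.30), miR-369-3p and miR-493 (1.27 ± 0.27). The list's adjusted p was 1.54e-16, and its adjusted p = 0.0864 with an estimated correlation. miR-9-5p averaged 43.4 ± 19.0 CPM in pericardial fat (2.48 ± 0.30, adjusted p = 3.46e-07), higher in 6 of 6 animals. miR-450b (1.45 ± 0.34) and miR-450a (1.25 ± 0.29) rose, 2 of 6 members of the miR-424 and miR-503 cluster and 5 over the list alone (adjusted p = 7.99e-04). Its adjusted p = 0.346 with an estimated correlation. miR-200b (3.29 ± 0.92) and miR-200a (3.10 ± 0.89) were higher in 5 of 6 animals. Their mean CPM was nevertheless higher in perirenal fat, 289 against 169 CPM for miR-200a and 25.1 against 16.9 CPM for miR-200b. For miR-200a that order rested on PRAT2, with 1562 CPM against 2.75 to 76.2 CPM in the other perirenal libraries. The mean log2 CPM of miR-200a was lower in perirenal (5.41) than in pericardial fat (6.32). In all 61 features differed, 45 higher and 16 lower, and 34 within letter B. The share higher was 73.8%, or 84.7% in limma and 48.2% in DESeq2. Without PCAT3 34 features and without PCAT6 36 features differed. The call of miR-200a ended without PCAT2 (3.00), PCAT3 (2.73) or PCAT6 (2.79), and that of miR-200b without PCAT3 (2.91) or PCAT6 (3.07) and within letter B (3.72). miR-200b stayed called at 4.02 without SSAT6 and 4.18 without IAT6, and miR-196a at −7.10 without PCAT3.

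**Figure D4:**
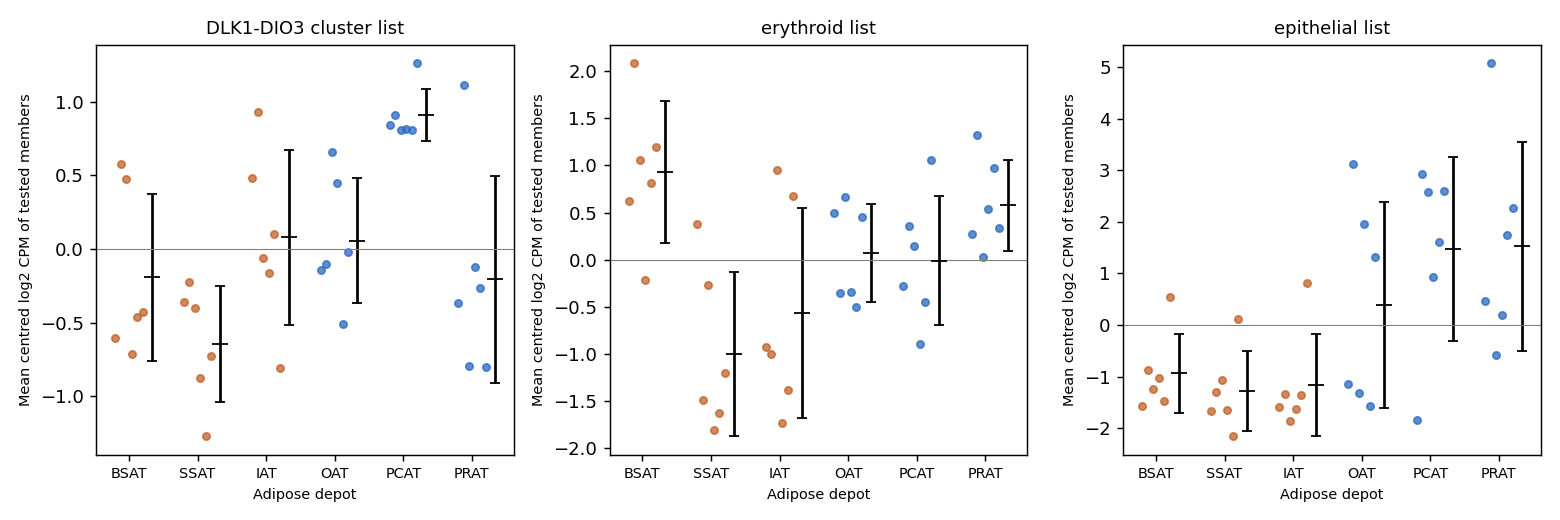
Mean centred log2 CPM of the tested members (y axis) of the DLK1-DIO3, erythroid and epithelial lists by depot (x axis), with 6 libraries per depot as points and the mean ± SD as bars. Pericardial fat stands above the other depots in the DLK1-DIO3 panel, where 18 of 36 members rose.

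Perirenal fat (PRAT) was high in epithelial miRNAs, in miR-122 and in the miR-196 pair, and low in miR-199b. Of 6 epithelial members 5 rose, 5 over the list alone: miR-200c (2.38 ± 0.43), miR-429 (4.14 ± 0.85), miR-200a (4.02 ± 0.88), miR-200b (3.97 ± 0.91) and miR-141 (2.02 ± 0.55). The list's adjusted p was 2.45e-04, and its adjusted p = 0.235 with an estimated correlation. Without PRAT2 and PRAT6 the list did not pass (adjusted p = 0.584). The mean score of the epithelial list was 1.52 ± 2.03 (SD, n = 6) in perirenal and 1.47 ± 1.78 in pericardial fat, so the rise was not particular to perirenal fat. miR-122, the main miRNA of liver, was higher in 6 of 6 animals (5.13 ± 0.84, adjusted p = 2.35e-04). miR-196a (3.32 ± 0.42), miR-196b (2.71 ± 0.46) and miR-10b (0.96 ± 0.21) rose, 3 of 5 HOX-cluster members and 4 over the list alone (adjusted p = 4.40e-09, and 4.67e-04 with an estimated correlation). The mean score of the HOX list was higher in inguinal (1.57) than in perirenal fat (1.33). miR-199b averaged 265 ± 35.8 against 719 ± 464 CPM (−1.27 ± 0.26, adjusted p = 0.00261) and was lower in 6 of 6 animals, as was NC_059165.1_25336 (−2.41 ± 0.60). The kidney and gut epithelium list, with 0 of 3 members called and 1 higher over the list alone, did not pass. In all 21 features differed, 18 higher and 3 lower, 10 within letter B and 73 with no filter. The share higher was 85.7%, or 67.7% in DESeq2. Without PRAT2 10 features differed and miR-429 (1.68) was not called, and without OAT2 33 features differed. miR-429 (3.48) was also not called with the letter as a covariate. Within letter B miR-429 was 2.21, miR-199b −1.18 and NC_059165.1_25336 −1.96, none called. NC_059165.1_25336 also lost its call without PRAT2 (−2.28). miR-122 reached 283 CPM in the perirenal library of animal 6, without which its value was 2.18, not called. Another candidate locus (2.64 ± 0.59, 4 of 6 animals higher) was 1.46 without PRAT3 and 1.87 with animals as blocks, neither called. With animals as blocks the DLK1-DIO3 list passed downward in this depot (adjusted p = 0.0436, and 0.0798 without blocks). Without blocks and with an estimated correlation that list did not pass either.

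Across all 6 depots 93 features differed in at least 1 depot, 43 within letter B and 170 in DESeq2. Among the 3 subcutaneous depots 4 features differed in a test of both contrasts at once: miR-196a (adjusted p = 0.00405), miR-451 (0.00843), miR-486 (0.0113) and the muscle miRNA miR-206 (0.0113). The means of miR-451 were 97855 ± 53610 CPM in back, 34814 ± 24359 CPM in inguinal and 19840 ± 11017 CPM in sternal fat. The 4 were named after their values were seen, as were miR-206 and miR-133b in back fat. Among the visceral depots 13 features differed, including miR-196a (adjusted p = 9.73e-09), miR-10b (4.99e-08), miR-196b (6.13e-08), miR-10a (8.50e-06), miR-9-5p (0.0406) and the DLK1-DIO3 miRNAs miR-411c-5p (0.0343), miR-411b (0.0406) and miR-369-3p (0.0406). With animals as blocks 7 features differed among the subcutaneous and 26 among the visceral depots, 5 and 9 within letter B, and 32 and 28 in DESeq2. Among the subcutaneous depots leaving out 1 library at a time gave 1 (without BSAT2) to 12 (without OAT6), with 10 without SSAT2 or PRAT6, 8 without SSAT1 or OAT2 and 7 without IAT6 or PCAT5. Among the visceral depots it gave 8 to 20, with 20 without OAT2 and 8 without any of BSAT1, BSAT2, BSAT5, SSAT6, IAT1, IAT6, OAT1, OAT3, PCAT1, PCAT5 or PRAT1.

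Of the 23 passing list tests, none changed the sign of its median under RLE factors, library totals, limma on RPM or DESeq2, but the size of some did not hold. The median of the brown and beige fat list between the classes fell from 0.21 to 0.00569 with library totals and 0.00308 in limma, and in inguinal fat from 0.21 to 0.13 and 0.06. That of the let-7 family in sternal fat fell from 0.37 to 0.12 and 0.11.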

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

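The test of the library letter was chosen only after the result was seen, what the test without the perirenal depot bears on was reworded after it, and the kidney and epithelial correlations were chosen before, with a condition on p added to their bounds afterwards.

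Groups of 6 values were checked, either the libraries of a depot or the differences of the 6 animals between the classes. Of 78 groups 4, all of libraries, had a value far from the other 5. Its gap, as a share of the group's whole range, exceeded the critical value of Dixon's test. Chance alone gives about 1 in 20. In pericardial fat PCAT1 had a log2 CPM of −2.64 for miR-200b against 2.39 to 5.08 in the others (gap 0.652). For miR-200a PCAT1 was at 0.91 against 5.82 to 8.34 (gap 0.660). The mean score of the epithelial list was 0.54 in BSAT6 against −1.56 to −0.88 in the other back libraries (gap 0.677). In IAT6 it was 0.82 against −1.87 to −1.34 in the other inguinal libraries (gap 0.802).

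miR-200a, miR-200b and miR-429, of the miR-200 family, were lower in subcutaneous than in visceral fat. The perirenal libraries alone were excluded as the source, since 3 of 3 kept their call without that depot (−4.77, −5.11 and −3.99), and the library letter was excluded as the whole cause, since the mean fold change kept 89.4% with the letter as a covariate. Kidney tissue in the 6 perirenal libraries met the bound set beforehand, a Spearman rho above 0.5 between the kidney list and the 3 miRNAs (0.829; Pearson's r = 0.893, exact permutation p = 0.0264, and 0.606 without the 2 farthest libraries), but is left open because it missed the condition added later (exact permutation p of rho = 0.0583), and kidney tissue in omental or pericardial fat, where the list's mean scores were −0.107 ± 0.273 and 0.0584 ± 0.343 (SD, n = 6), is open too. Epithelial cells that bring all epithelial miRNAs also stay open over the 18 visceral libraries (rho = 0.470, permutation p = 0.0507; r = 0.602, p = 0.00855, and 0.651 without the 2 farthest), with the 3 other tested members below the bound for a cause and above that against it. Those other members, miR-141, miR-183 and miR-200c, averaged 1.73, 1.94 and 8.55 CPM, and miR-183 pointed the other way between the classes. This correlation therefore rests on low counts and cannot decide the question. A difference between the depots themselves is a further open explanation that was not tested.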

How the results depend on the processing

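Alternatives added after the data were seen were those without BSAT2, without PRAT2 and PRAT6, without a depot or single libraries, and with miR-26a and miR-26c summed. Over the alternatives other than single libraries left out, 890 of 1110 values of named miRNAs kept direction and side of the threshold, 204 lost the call and 16 turned; of 211 counts, 151 stayed within 1.5 times and 60 did not. Of 51 named calls 11 held under every alternative run for them, 23 for the classes and 18 for the depots, which were not run with 2 groups of 18 libraries, summed counts or a depot left out: miR-27a-5p, miR-23a, miR-199b, miR-200a, miR-429 and miR-9-5p between the classes, the miR-196 pair in inguinal and pericardial fat, and miR-9-5p in pericardial fat. The replicate block, which keeps 41 of 51, and the list calls it moved stand beside their results; it changed no other call of a named miRNA or list. The causes of the changes below were not tested, except that fewer libraries or features enter some settings. How sequencing depth bears on the calls was not tested.

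With library totals alone 20 features were called in omental fat and 10 among the subcutaneous depots. With no filter there were 40 in back, 30 in sternal, 21 in inguinal, 126 in omental and 73 in perirenal fat and 7 among the visceral depots. A mean of at least 10 CPM gave 15 among the subcutaneous depots. The replicate block gave 3 in omental fat, 7 among the subcutaneous and 26 among the visceral depots. The letter as a covariate gave 71 between the classes, and letter B alone 39, with 25 in sternal, 2 in omental, 34 in pericardial and 10 in perirenal fat and 43 over all depots. Without BSAT2 there were 7 in back fat, 1 among the subcutaneous and 8 among the visceral depots. Without PRAT2 and PRAT6 there were 97 between the classes and 14 in perirenal fat. limma gave 7 among the subcutaneous depots. DESeq2 gave 97 in sternal and 19 in omental fat, 170 over all depots, 32 among the subcutaneous and 28 among the visceral depots. Counts summed per animal and class gave 23, or 46 with the replicate block, and without the pericardial depot 54 were called. With an estimated correlation 1 list passed between the classes and 4 over the depots.

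Leaving out each animal gave 56 to 101 calls between the classes, 40 to 84 over all depots, 7 to 15 in back, 16 to 69 in sternal, 2 to 3 in inguinal, 1 to 13 in omental, 30 to 74 in pericardial and 13 to 26 in perirenal fat. It gave 0 to 8 among the subcutaneous (edgeR) and 6 to 15 among the visceral depots, and 4 to 5 and 14 to 25 lists. Of the 51 named calls 22 held without each animal. Between the classes NC_059178.1_42973 and let-7c were lost in 4 of 6 fits, miR-138 and miR-615 in 3, let-7i, miR-142-5p, miR-214 and NC_059163.1_21335 in 2, and miR-122, miR-148c and miR-2285bb in 1. In back fat miR-1247-5p, miR-218 and miR-223 were lost in 5, miR-451 in 2 and miR-486 in 1. In sternal fat miR-138 and miR-370 were lost in 6, the other locus in 2, and miR-148c and NC_059178.1_42973 in 1. In omental fat it was miR-23a in 4 and miR-142-3p and NC_059163.1_21335 in 3, in pericardial fat miR-200a in 3 and miR-200b in 2, and in perirenal fat NC_059165.1_25336 in 3 and miR-429 and the other locus in 1.

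limma lost 17 named calls: NC_059178.1_42973, miR-148c, miR-214, miR-122, let-7c and let-7i between the classes, miR-451, miR-223 and miR-1247-5p in back fat, NC_059178.1_42973, miR-148c, the other locus and miR-138 in sternal fat, miR-142-3p and NC_059163.1_21335 in omental fat, and miR-429 and the other locus in perirenal fat. With no filter 7 were lost: NC_059178.1_42973, let-7c and let-7i between the classes, the other locus, miR-138 and miR-370 in sternal fat and miR-200a in pericardial fat. The letter as a covariate ended 4, NC_059178.1_42973, let-7c and let-7i between the classes and miR-429 in perirenal fat. Library totals ended 3, let-7c and let-7i between the classes and miR-223 in back fat. RLE factors, and the sum of miR-26a and miR-26c, each ended 1, miR-138 in sternal fat, and DESeq2 1, miR-200b in pericardial fat. Without PRAT2 and PRAT6 7 ended: NC_059178.1_42973 and let-7i between the classes, miR-138 in sternal, miR-23a in omental, and miR-122, miR-429 and NC_059165.1_25336 in perirenal fat. Without BSAT2 6 ended: miR-486, miR-451, miR-223, miR-1247-5p and miR-218 in back fat and miR-138 in sternal fat.

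Between the classes miR-10a was −0.11 without the pericardial depot, miR-26a −0.11 with the letter as a covariate and between −0.0317 (without animal 5) and 0.477 over the animals left out, and miR-451 0.0120 summed per animal. The most abundant candidate locus, at −0.01, was 0.0145 with RLE factors, 0.0121 with no filter, 0.00894 at 10 CPM or more, 0.0131 with the replicate block, 0.0483 without BSAT2, 0.0141 in DESeq2, 0.00400 summed and 0.0212 summed with the block. Over the animals left out it was between −0.239 and 0.199, above 0 without each of animals 1 to 4.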

Other observations

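The contrasts between single depots, the miR-26 tests and the miR-206 test were chosen only after the values were seen, while the splits of the labels were planned.

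Perirenal fat, a visceral depot, was near the subcutaneous depots in HOX-cluster miRNAs. Perirenal minus the mean of the 3 subcutaneous depots was 1.22 ± 0.50 (SE) for miR-196a (edgeR adjusted p = 0.149), 0.38 ± 0.56 for miR-196b (0.733), 0.17 ± 0.23 for miR-10b (0.724), 0.09 ± 0.30 for miR-10a (0.888) and −0.69 ± 0.62 for miR-615 (0.565), none past the threshold, which does not show that they were equal. Omental fat was above pericardial fat in all 5 members, 4 of them past the threshold: miR-10a by 2.75 ± 0.39 (edgeR adjusted p = 2.12e-05), miR-10b by 1.69 ± 0.30 (5.03e-04), miR-196a by 3.41 ± 0.73 (0.00804) and miR-615 by 3.50 ± 0.88 (0.0389). miR-615 had 0 counts in 5 of 6 pericardial libraries, so the size of its difference is uncertain. miR-196b was at 2.53 ± 0.75 (0.0809).

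miR-26a and miR-26c replaced each other between libraries. The SD of log2 CPM was 1.64 for miR-26a, 2.10 for miR-26c and 0.350 for their sum, 21.4% of the smaller, so a candidate explanation is that the same reads were counted under either entry. This explanation was reworded after its result was seen, and sequences were not used. The letter (permutation p = 0.108), the animal (0.767) and the depot (0.827) were excluded as what sets which entry is high, since shares of miR-26a both over 90% and under 10% occurred in 2 of 2 letters, 5 of 6 animals and 4 of 6 depots. No biological explanation was tested.

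miR-206, a skeletal muscle miRNA, was higher in back fat by 4.12 ± 0.69 (edgeR adjusted p = 5.94e-04). Without BSAT2 it was −0.17 ± 0.67, so −4.22% of the value was kept. BSAT2 held 2228 CPM of miR-206, against 2.20 to 70.5 CPM in the other back libraries, and 4 of 6 tested muscle miRNAs had their highest or second highest level of 36 libraries there. Skeletal muscle in that sample may account for the difference. miR-208b, with 0 CPM, and miR-499, with 13.2 CPM, were not raised there, and no biological explanation was tested.

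Depot labels were shuffled inside animals to give 100 splits, the real one included. Chance can be excluded for subcutaneous against visceral, where 1 of 100 splits gave as many calls (110, highest other 5), and over all depots, with 1 split (93 calls, highest other 7). It can also be excluded for pericardial fat, with 1 split (61 calls, highest other 19), and among the visceral depots, with 1 (13, highest other 4). Sternal fat had 1 split (62 calls, highest other 21). As few as 16 sternal features were called with 1 animal left out and 22 without SSAT4, so chance is left open there. Labels shuffled over all libraries gave up to 13 calls between the classes, 37 over all depots, 58 in sternal and 30 in pericardial fat. Shuffled over the libraries of each class, 2 of 100 splits, the real one included, reached the 13 visceral calls (highest other 16). Perirenal fat, with 3 splits (21 calls, highest other 26), was under the bound of 5 splits set beforehand. A shuffled split still gave more calls than the real labels there. Only 10 perirenal features were called without PRAT2, so chance is left open for this depot. For the number of calls chance cannot be excluded in back fat, with 5 splits (15 calls, highest other 30), inguinal fat, with 23 (2, highest other 45), omental fat, with 7 (10, highest other 29), or among the subcutaneous depots, with 5 (4, highest other 9). This bears on how many were called, not on the 2 inguinal calls themselves: miR-196a (4.21 ± 0.41, edgeR adjusted p = 5.03e-09) and miR-196b (3.07 ± 0.46, edgeR adjusted p = 3.66e-05) were higher in 6 of 6 animals and stayed called without any 1 of the 36 libraries. The 2 inguinal calls compare with a mean that includes the low omental and pericardial depots, and do not set inguinal against perirenal fat alone. The lists passed often under shuffled labels, with a median of 2 between the classes and 12 over the depots. Chance is thus not excluded for the count of 5 lists between the classes (9 of 100, highest other 7) or of 18 over the depots (10 of 100, highest other 21).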
